A study of Homo sapiens with 18 samples.

How the data were processed

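RNA sequencing of HEK293T cells was deposited as 2 tables of gene values per library, 1 for 6 total RNA libraries and 1 for 12 libraries of nuclear and cytoplasmic RNA. The 18 libraries fall into 6 groups of 3 replicates: total, nuclear and cytoplasmic RNA, each from cells given an siRNA against FAM32A or a control siRNA. Per the labels, the authors aligned reads to GRCh38 with HISAT2 and counted them per gene with featureCounts. Versions, annotation release, strand setting and filters are not stated, and neither are the siRNA sequences. Because the strand of counting is unknown, values of overlapping and antisense genes remain uncertain, and so do those of near-identical paralogs such as HSPA1A and HSPA1B and of ribosomal protein genes, which have many pseudogenes.

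The unit of the deposited values differs from the name the authors gave it. The values, named TPM by the authors, were not whole, and every library summed to the same total over all listed genes. The smallest step between a gene's values rose with its annotated exon length, with a Spearman correlation of 0.959 over 4277 genes of the total RNA table and 0.916 over 8031 genes of the fraction table. The deposited values were therefore read as counts multiplied by gene length and scaled to that total, where TPM divides by length. Each gene's step was divided out to recover whole reads. At a tolerance of 0.1 reads, 99.996% to 100% of the recovered values per library were whole. In the fraction table most values were even multiples of a smaller unit: even values made up 50.6% to 59.7% of the recovered values from 1 to 10, against 35.1% to 36.3% in total RNA. The most frequent step was divided by 2 there, a choice that does not move CPM. The recovered depth was 19.8 to 20.1 M reads per total RNA library and 36.8 to 67.7 M per fraction library. In data simulated as whole reads times annotated length, the recovery returned the simulated count for 98.1% of the nonzero values of total RNA and 99.9% of those of the fractions. The simulation used the annotated lengths throughout and no smaller unit. It therefore does not test the recovery where the real tables depart from these. Counting error was smaller than replicate spread: between replicates of a group, the chi-square per degree of freedom over genes with 50 or more reads ran from 3.14 to 50.5.

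Recovered reads were divided by each library's depth in M reads to give CPM. Symbols and coordinates came from GENCODE 29 on GRCh38, which named 61756 of 61859 listed identifiers in total RNA and 62539 of 70609 in the fractions. The annotation the authors used is not stated, and GENCODE 29 lengths lay within 5% of the recovered ones for 74.2% and 73.5% of the genes compared. Genes entered a comparison with a mean of 1 CPM or more in some group, which left 15139 genes in total RNA and 17254 in the fractions. A log2 of CPM + 1 was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend), total RNA by itself and the 4 fraction groups together with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The nuclear-to-cytoplasmic ratio contrast is the nuclear log2 fold change minus the cytoplasmic one, and it tests the difference between the fractions itself. All p values are two-sided, and SE stands for limma's standard error of a log2 fold change.

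The comparisons, the test, the gene lists and the rule for named genes were chosen before the data were examined. The intended count-based test was planned for counts as given, which the files do not hold. The limma fit fixed as its fallback was therefore used. That fallback was worded for the values in the files, and its use on recovered reads was chosen after their unit was examined. Each list was tested against all other genes with camera (preset correlation 0.01), adjusted over the 36 of 39 lists with enough measured genes, beside camera with an estimated correlation and fry. With an estimated correlation none of the 73 list calls over the 5 comparisons kept an adjusted p under 0.05, so each list below carries that p. The text names FAM32A first, then for each siRNA comparison and for the ratio the 6 largest rises and the 6 largest falls among called genes. These had a mean of 5 CPM or more in the higher group and a symbol that is not a clone name. In the 3 siRNA comparisons all 3 knockdown libraries also had to lie on the same side of all 3 control libraries, which chance gives for 10% of genes. Up to 4 called members with the smallest adjusted p represent a list, and the 5 most nuclear and 5 most cytoplasmic genes above 20 CPM represent the control fractions. A symbol shared by several genes was left out, and a few genes that the rule names are not printed because they are withheld for evaluation.

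Replicate numbers pair libraries only where residuals of the same number go together. This held between the cytoplasmic control and knockdown libraries, with correlations of 0.17, 0.49 and 0.46 against at most 0.04 for other numbers. It held for no other pair of groups examined. With 3 libraries per group chance can give such a match, so a true pairing is not established. For the cytoplasmic libraries a fit with the replicate as a block was added after the data were seen.

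A search for short words was chosen after the data were seen. Every 7-base and 6-base word present in the annotated 3′ UTR of at least 100 genes was scored on the log2 fold changes of genes that have it against those that lack it, over 12244 genes in total RNA and 12878 in the fractions. UTRs shorter than 50 bases and genes with no annotated 3′ UTR were not searched. Differences between site classes are medians against genes without a site of matched 3′ UTR length. Their intervals come from 1000 bootstrap draws of genes and leave out the spread between libraries. To keep the choice of words apart from their test, words were also chosen on a random set of 6439 genes and scored on the other 6439, in cytoplasmic RNA.

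Alternatives chosen before the data were seen were a pseudocount of 0.1, no filter, a filter of 5 CPM, median-of-ratios scaling, voom weights in total RNA and the ratio, a replicate block, each fraction fitted alone, mitochondrial genes left out, and each library left out in turn. Added after the data were seen were quantile normalization, voom weights in the other comparisons, and leaving out genes with the words found. The deposited values as they stand were fitted too, which is the fallback as it had been worded. On data simulated with the real levels at a dispersion of 0.01, the fit called 81%, 89%, 88% and 40% of genes changed 1.5-fold in total, nuclear and cytoplasmic RNA and in the ratio, and 98% to 100% of those changed 2-fold. Exact permutation tests compare shares of reads between groups of 3, where the smallest two-sided p is 0.1. Other software was python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.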

Results

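Polyadenylated RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after transfection of an siRNA against FAM32A or a control siRNA. FAM32A encodes a small protein known from structures of the human spliceosome in its late, catalytic stages. Total RNA, nuclear RNA and cytoplasmic RNA were each measured in 3 FAM32A siRNA and 3 control siRNA libraries. The titles give 24 hours for total RNA and no time for the fractions, while the series description gives 24 hours for the knockdown cells. Total RNA libraries held 19.8 to 20.1 M recovered reads, with 14708 to 15040 genes at 1 CPM or more. Fraction libraries held 36.8 to 67.7 M, with 13944 to 16869 such genes. No spike-in is named in the labels, so every change is relative to the other RNA of the same library.

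FAM32A mRNA (ENSG00000105058, chromosome 19, 16185380 to 16192046, plus strand, GRCh38) fell in all 3 RNA preparations. In total RNA it went from 62.5 ± 2.30 CPM (SD, n = 3) in control cells to 11.8 ± 0.232 CPM (SD, n = 3), 18.9% of control, with a log2 fold change of -2.31 ± 0.08 (SE) and an adjusted p of 4.75e-07. In cytoplasmic RNA it went from 36.0 ± 2.78 to 12 ± 0.696 CPM (33.4% of control, log2 fold change -1.50 ± 0.09, adjusted p = 7.36e-10). In nuclear RNA the fall was from 21.1 ± 2.32 to 16.2 ± 0.893 CPM (76.5% of control, log2 fold change -0.36 ± 0.09, adjusted p = 0.0027). All 3 knockdown libraries lay below all 3 control libraries in each preparation. On the deposited values as they stand, the nuclear fall was -0.24 with an adjusted p of 0.055. The difference between nuclear and cytoplasmic change was 1.14 ± 0.12 (adjusted p = 3.53e-05). FAM32A lay further below control in total RNA than in either fraction. Whether the knockdown itself differed between total RNA and fractions was not tested, so an equal knockdown cannot be assumed where they are compared.

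**Figure D1:**
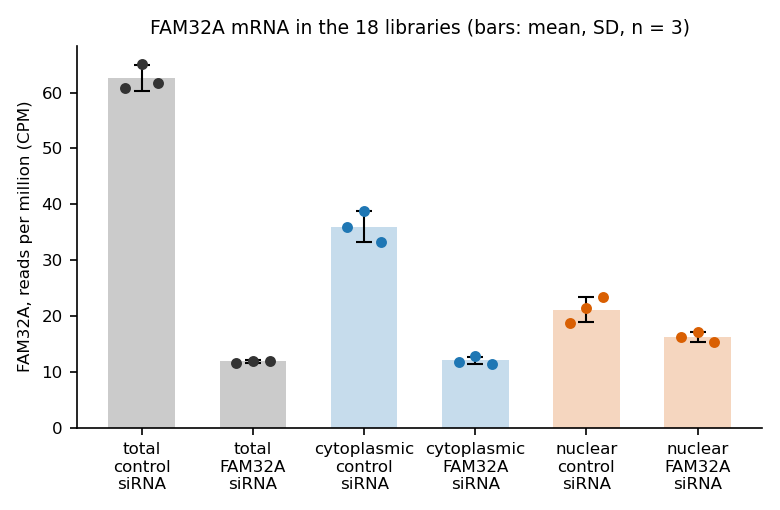
FAM32A level in CPM in the 18 libraries, as points, with the group mean (bar) and SD (whisker, n = 3). Means fell from 62.5 to 11.8 CPM in total RNA, from 36.0 to 12 CPM in the cytoplasm and from 21.1 to 16.2 CPM in the nucleus.

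In total RNA the question was which transcripts change when FAM32A is depleted. Besides FAM32A, the largest falls were those of FAM3C, a secreted cytokine-like protein (-2.41 ± 0.13, 56.1 ± 5.74 to 9.79 ± 1.75 CPM), and HSPA1A, the inducible HSP70 chaperone (-2.01 ± 0.20, 92.1 ± 14.1 to 22.7 ± 7.33 CPM). SLC7A11, the cystine transporter, fell by 1.76 ± 0.09 on the log2 scale (62.3 ± 5.42 to 17.7 ± 0.978 CPM). MOCS2, a molybdenum cofactor enzyme (-1.73 ± 0.10), TTC7B, part of a plasma membrane lipid kinase complex (-1.73 ± 0.10), and BTBD1 (-1.65 ± 0.09) followed. The largest rises were NTN1, the guidance cue netrin-1 (1.80 ± 0.13, 20.9 ± 3.14 to 75.1 ± 10.7 CPM), and PIP4K2A, a phosphoinositide kinase (1.42 ± 0.08, 27.3 ± 1.53 to 74.4 ± 2.16 CPM). The receptor tyrosine kinases KIT (1.24 ± 0.10) and MET (1.17 ± 0.08) rose too, as did CALU, a calcium-binding protein of the secretory pathway (1.24 ± 0.07), and SLC36A1, an amino acid transporter (1.20 ± 0.10). Adjusted p values of these 12 genes ran from 7.71e-06 to 0.000338.

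Of 15139 genes tested in total RNA, 646 were higher and 679 lower, with 16 and 30 of them changed at least 2-fold. Single libraries moved these counts. Without control replicate 1 they were 1441 and 1080, and without knockdown replicate 3 they were 1285 and 1087. Leaving out control replicate 2 gave 296 and 393, control replicate 3 gave 163 and 269, knockdown replicate 1 gave 196 and 309, and knockdown replicate 2 gave 169 and 297. With no filter on low values they were 279 and 405.

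Chaperone genes of the heat shock response fell as a group in total RNA. Of 15 members, 5 fell and 0 rose (11 fell when adjusted over the list alone), with a median of -0.27, an adjusted p of 4.03e-07 and an adjusted p = 0.313 with an estimated correlation. Besides HSPA1A these were HSPA1B (-0.67 ± 0.08), whose reads cannot be fully separated from it, and the constitutive HSPA8 (-0.57 ± 0.07). The list did not pass in nuclear RNA (median -0.04, adjusted p = 0.493) or cytoplasmic RNA (median -0.10, adjusted p = 0.099). Targets of p53, a protein that large T antigen binds in these cells, rose as a group. Of 21 members 6 rose and 0 fell (9 and 0 when adjusted over the list alone), with a median of 0.22 (adjusted p = 0.000435, and adjusted p = 0.313 with an estimated correlation). The cell cycle inhibitor CDKN1A led them (1.01 ± 0.15, adjusted p = 0.00354).

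Targets of ATF4, the transcription factor of the integrated stress response, fell in 7 of 25 cases and rose in 2 (11 and 3 when adjusted over the list alone). Their median was -0.15 (adjusted p = 0.0061, and adjusted p = 0.607 with an estimated correlation), and without knockdown replicate 3 the adjusted p was 0.0712. ATF4 itself (-0.41 ± 0.06) and PSAT1, a serine synthesis enzyme (-0.44 ± 0.07), were among the falls. Endoplasmic reticulum (ER) chaperones rose in 4 of 17 cases and fell in 1 (6 and 1 when adjusted over the list alone), led by the protein disulfide isomerase PDIA4 (1.03 ± 0.07) and SEL1L, a scaffold of ER-associated degradation (0.74 ± 0.08). Their adjusted p was 0.0109 (adjusted p = 0.816 with an estimated correlation), and 0.192 without genes that hold the sites described further on.

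Small shifts of larger groups also passed in total RNA. Changes in total RNA followed transcript GC content across genes (Spearman's rho = 0.447), and no gene list was matched for it. Cytosolic ribosomal protein mRNAs had a median of -0.10 (adjusted p = 0.000189), with 3 of 79 fallen and 0 risen (3 and 0 when adjusted over the list alone), RPS26 by far the most (-1.55 ± 0.08). The 13 mitochondrially encoded mRNAs had a median of 0.44 (adjusted p = 0.000534), with 2 risen and 0 fallen (7 and 0 when adjusted over the list alone). For both lists the adjusted p = 0.816 with an estimated correlation. As a share of reads, the mitochondrial mRNAs took 2.86% ± 0.401 (SD, n = 3) after FAM32A siRNA and 2.28% ± 0.597 in control cells (exact permutation p = 0.3). Control replicate 1 (2.93%) lay with knockdown replicates 1 (3.27%) and 2 (2.83%), above knockdown replicate 3 (2.47%) and control replicates 2 (1.76%) and 3 (2.13%). Setting the same 3 libraries against the other 3 called 1411 genes, against 1325 for the siRNA. Lists of G1/S genes (1 of 26 fell, median -0.13, adjusted p = 0.00557), mitotic genes (3 of 28, median -0.12, adjusted p = 0.0061) and snoRNA host genes (4 of 18, median -0.20, adjusted p = 0.0061) shifted down with no riser. Adjusted over the list alone, 4, 3 and 7 fell and 0, 1 and 0 rose, and for all 3 lists the adjusted p = 0.816 with an estimated correlation. CDC25C (-0.56 ± 0.08) and CCNA2 (-0.48 ± 0.08), regulators of mitotic entry, and SNHG4 (-0.54 ± 0.08) were among the falls.

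In cytoplasmic RNA, where mRNA is translated, SLC7A11 had the largest fall (-2.49 ± 0.14, 123 ± 32.6 to 20.6 ± 1.42 CPM). FAM3C (-2.04 ± 0.07, 65.8 ± 1.14 to 15.2 ± 1.28 CPM) and CHAC1, a glutathione-degrading enzyme and ATF4 target (-2.03 ± 0.28, 7.83 ± 2.96 to 1.10 ± 0.360 CPM), came next. MOCS2 (-1.86 ± 0.10), TTC7B (-1.62 ± 0.07) and GREB1L (-1.56 ± 0.08) followed. NTN1 (1.83 ± 0.11, 12.5 ± 1.44 to 47.1 ± 4.99 CPM) and PIP4K2A (1.72 ± 0.07, 30.1 ± 0.346 to 101 ± 5.52 CPM) rose most. SLC36A1 (1.55 ± 0.08), CALU (1.52 ± 0.07), KIT (1.47 ± 0.07) and LZTFL1, a regulator of ciliary transport (1.43 ± 0.07), rose as well. The adjusted p of CHAC1 was 2.97e-05, and those of the other 11 genes ran from 7.7e-12 to 7.84e-10.

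**Figure D2:**
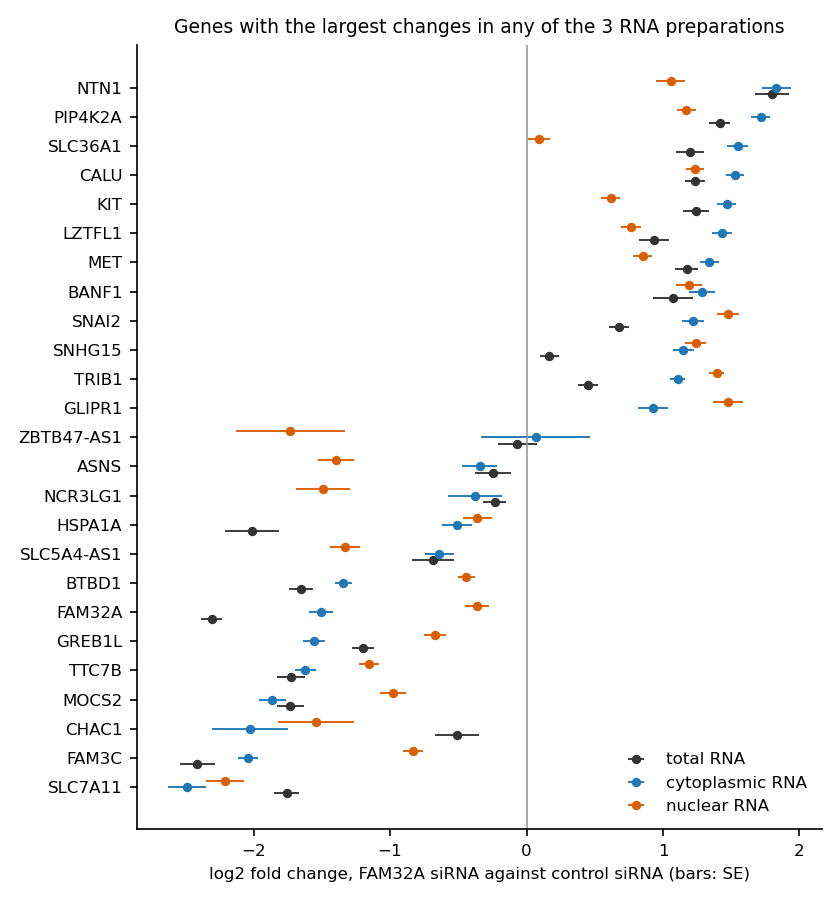
Log2 fold change (FAM32A siRNA against control siRNA) with SE of the genes with the largest changes in total RNA (black), cytoplasmic RNA (blue) or nuclear RNA (orange), from limma with n = 3 per group. FAM3C fell by 2.41 in total RNA, by 2.04 in the cytoplasm and by 0.83 in the nucleus, while SLC36A1 rose in the first 2 and stood at 0.09 in the nucleus.

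Of 17254 genes tested in cytoplasmic RNA, 1793 were higher and 2560 lower, 42 and 44 of them at least 2-fold. Median-of-ratios scaling gave 2884 and 1918. With the cytoplasmic libraries paired by replicate number in a fit of their own, 2768 were higher and 3810 lower. Without that pairing, which is not established, the fit of these libraries alone gave 1910 and 2747.

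ATF4 targets fell in 15 of 24 cases in the cytoplasm and rose in 1 (16 and 1 when adjusted over the list alone), with a median of -0.33. The adjusted p was 2.33e-05, and adjusted p = 0.567 with an estimated correlation. ATF4 (-0.69 ± 0.08) and the tRNA exporter XPOT (-0.44 ± 0.06) fell with SLC7A11 and CHAC1. Targets of p53 rose in 11 of 21 cases and fell in 0 (11 and 0 when adjusted over the list alone), with a median of 0.18 (adjusted p = 0.00142, and adjusted p = 0.41 with an estimated correlation). They included TP53INP1 (0.55 ± 0.07), ZMAT3 (0.54 ± 0.07) and SESN1 (0.51 ± 0.07). CDKN1A, named here because of its change in total RNA, rose by 0.72 ± 0.10 (adjusted p = 5.19e-05).

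Transcripts for splicing proteins rose modestly in the cytoplasm. Late-stage splicing factors rose in 13 of 34 cases and fell in 3 (14 and 4 when adjusted over the list alone), with a median of 0.10 (adjusted p = 0.00462, and adjusted p = 0.41 with an estimated correlation). CWC15 (0.79 ± 0.09) and RBM22 (0.43 ± 0.05), both proteins of the catalytic spliceosome, rose most clearly. Core snRNP and spliceosome proteins rose in 8 of 37 cases and fell in 1 (6 and 0 when adjusted over the list alone), among them SNRPD3 (0.50 ± 0.06), with an adjusted p of 0.00381 and adjusted p = 0.567 with an estimated correlation. The hnRNP proteins rose in 6 of 25 cases and fell in 0 (6 and 0 when adjusted over the list alone), among them PTBP1 (0.31 ± 0.05), with an adjusted p of 0.00462 and adjusted p = 0.573 with an estimated correlation.

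Other cytoplasmic list shifts were less firm. G1/S and DNA replication genes fell in 9 of 26 cases and rose in 2 (10 and 2 when adjusted over the list alone), led by the transcription factor E2F1 (-0.76 ± 0.08) and the chromatin assembly factor CHAF1B (-0.40 ± 0.06). Their adjusted p of 0.0268 (adjusted p = 0.654 with an estimated correlation) rose to 0.122 with median-of-ratios scaling, 0.087 on the deposited values and 0.051 with a filter of 5 CPM. Genes of cholesterol synthesis and uptake rose in 7 of 21 cases and fell in 3 (8 and 3 when adjusted over the list alone), led by INSIG1 (0.70 ± 0.06) and the rate-limiting epoxidase SQLE (0.34 ± 0.05). Their adjusted p was 0.0268 (adjusted p = 0.567 with an estimated correlation), and it was 0.0557 with a filter of 5 CPM, 0.0577 with quantile normalization and 0.0731 without knockdown replicate 2.

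In nuclear RNA the largest falls were again led by SLC7A11 (-2.21 ± 0.14, 92.6 ± 11.5 to 19.2 ± 1.74 CPM). The ATF4 targets CHAC1 (-1.54 ± 0.28) and ASNS, asparagine synthetase (-1.40 ± 0.13, 11.4 ± 1.99 to 3.67 ± 0.566 CPM), were among them, as was NCR3LG1, ligand of a natural killer cell receptor (-1.49 ± 0.20). The antisense transcripts ZBTB47-AS1 (-1.73 ± 0.40, 8.33 ± 8.20 to 1.22 ± 0.605 CPM) and SLC5A4-AS1 (-1.33 ± 0.11) completed them. SNAI2, the transcription factor Slug (1.48 ± 0.08, 21.8 ± 2.37 to 62.1 ± 2.86 CPM), GLIPR1 (1.48 ± 0.11) and the pseudokinase TRIB1 (1.39 ± 0.06, 39.1 ± 1.72 to 104 ± 1.82 CPM) rose most. SNHG15, a snoRNA host transcript (1.24 ± 0.08), CALU (1.23 ± 0.07) and BANF1, a chromatin-binding protein (1.19 ± 0.10), followed. The adjusted p of ZBTB47-AS1 was 0.00211 and that of CHAC1 0.00029, and those of the other 10 genes ran from 4.47e-11 to 1.76e-05.

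Of the 17254 genes, 3674 were higher and 4405 lower in nuclear RNA, 47 and 50 of them at least 2-fold. This split turned with the scaling: median-of-ratios scaling gave 5057 higher and 3074 lower, and the deposited values 4503 and 2657.

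mRNAs of the respiratory chain and the ribosome rose in the nucleus. Subunits of the respiratory chain rose in 38 of 66 cases and fell in 1 (46 and 1 when adjusted over the list alone), with a median of 0.31 (adjusted p = 1.16e-08, and adjusted p = 0.446 with an estimated correlation). ATP5MG (1.03 ± 0.10) and NDUFS8 (0.67 ± 0.08) are examples. Cytosolic ribosomal proteins rose in 43 of 79 cases and fell in 1 (46 and 1 when adjusted over the list alone), with a median of 0.29 (adjusted p = 2.16e-08, and adjusted p = 0.54 with an estimated correlation). RPS10 (1.08 ± 0.09), which shares exons with an annotated read-through gene, is an example. Ribosome biogenesis factors rose in 16 of 30 cases and fell in 1 (17 and 1 when adjusted over the list alone), with a median of 0.19. The list had an adjusted p of 1.45e-05 and adjusted p = 0.161 with an estimated correlation, and RRS1 (0.59 ± 0.06) and dyskerin, DKC1 (0.45 ± 0.05), were among the risers. In the same libraries mitochondrially encoded mRNAs rose in 7 of 13 cases and fell in 0 (7 and 0 when adjusted over the list alone), with a median of 0.32 (adjusted p = 0.0108, and adjusted p = 0.581 with an estimated correlation). The adjusted p was 0.0648 without nuclear knockdown replicate 1 and 0.0673 without nuclear control replicate 2. They took 2.62% ± 0.344 (SD, n = 3) of nuclear reads after FAM32A siRNA and 2.26% ± 0.303 in control cells (exact permutation p = 0.3).

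Transcripts for RNA processing proteins also rose in the nucleus. Late-stage splicing factors, a list that does not include FAM32A, rose in 20 of 34 cases and fell in 0 (21 and 0 when adjusted over the list alone), with a median of 0.19 (adjusted p = 4.56e-06, and adjusted p = 0.106 with an estimated correlation). CWC22 (0.76 ± 0.05), SYF2 (0.65 ± 0.08) and SNW1 (0.46 ± 0.05) were among them. Core snRNP and spliceosome proteins rose in 27 of 37 cases and fell in 1 (28 and 1 when adjusted over the list alone), with a median of 0.22 (adjusted p = 2.6e-06, and adjusted p = 0.161 with an estimated correlation). SNRPB (0.51 ± 0.09) and SNRNP40 (0.40 ± 0.06) are examples. The hnRNP proteins rose in 19 of 25 cases and fell in 1 (19 and 1 when adjusted over the list alone), with a median of 0.24 (adjusted p = 2.6e-06, and adjusted p = 0.207 with an estimated correlation). SYNCRIP (0.43 ± 0.06) and HNRNPAB (0.44 ± 0.07) are examples.

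Long non-coding transcripts fell in the nucleus. Of 7 nuclear-retained long non-coding RNAs, 5 fell and 0 rose (5 and 0 when adjusted over the list alone), with a median of -0.61. The paraspeckle scaffold NEAT1 (-0.67 ± 0.10), the speckle RNA MALAT1 (-1.07 ± 0.18), MIAT (-0.61 ± 0.13) and TUG1 (-0.38 ± 0.08) were among them. The adjusted p was 0.0112, and adjusted p = 0.161 with an estimated correlation. Antisense genes named -AS fell in 214 of 567 cases and rose in 54 (216 and 55 when adjusted over the list alone), with a median of -0.21 (adjusted p = 0.000379, and adjusted p = 0.21 with an estimated correlation). Among genes named LINC, 112 of 245 fell and 10 rose (113 and 10 when adjusted over the list alone), with a median of -0.28 (adjusted p = 3.09e-06, and adjusted p = 0.161 with an estimated correlation). With no filter on low values the LINC list had an adjusted p of 0.0619. Values of antisense genes may include reads of the genes they overlap.

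Stress-related lists moved in the nucleus as well. ATF4 targets fell in 13 of 24 cases and rose in 1 (14 and 1 when adjusted over the list alone), with a median of -0.27 (adjusted p = 0.000706, and adjusted p = 0.446 with an estimated correlation). Targets of p53 rose in 12 of 21 cases and fell in 1 (12 and 1 when adjusted over the list alone), with a median of 0.18 (adjusted p = 0.000458, and adjusted p = 0.161 with an estimated correlation). BAX, which permeabilises mitochondria in apoptosis (0.65 ± 0.08), and the nuclease AEN (0.53 ± 0.06) are examples. ER chaperones rose in 12 of 17 cases and fell in 1 (12 and 1 when adjusted over the list alone), with a median of 0.20 (adjusted p = 0.000706, and adjusted p = 0.161 with an estimated correlation). PDIA4 rose by 0.90 ± 0.05, and HYOU1, an ER chaperone of the HSP70 class, changed by -0.65 ± 0.08. Cholesterol genes rose in 8 of 21 cases and fell in 0 (8 and 0 when adjusted over the list alone), among them INSIG1 (0.70 ± 0.06), with an adjusted p of 0.00405 and adjusted p = 0.161 with an estimated correlation.

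**Figure D3:**
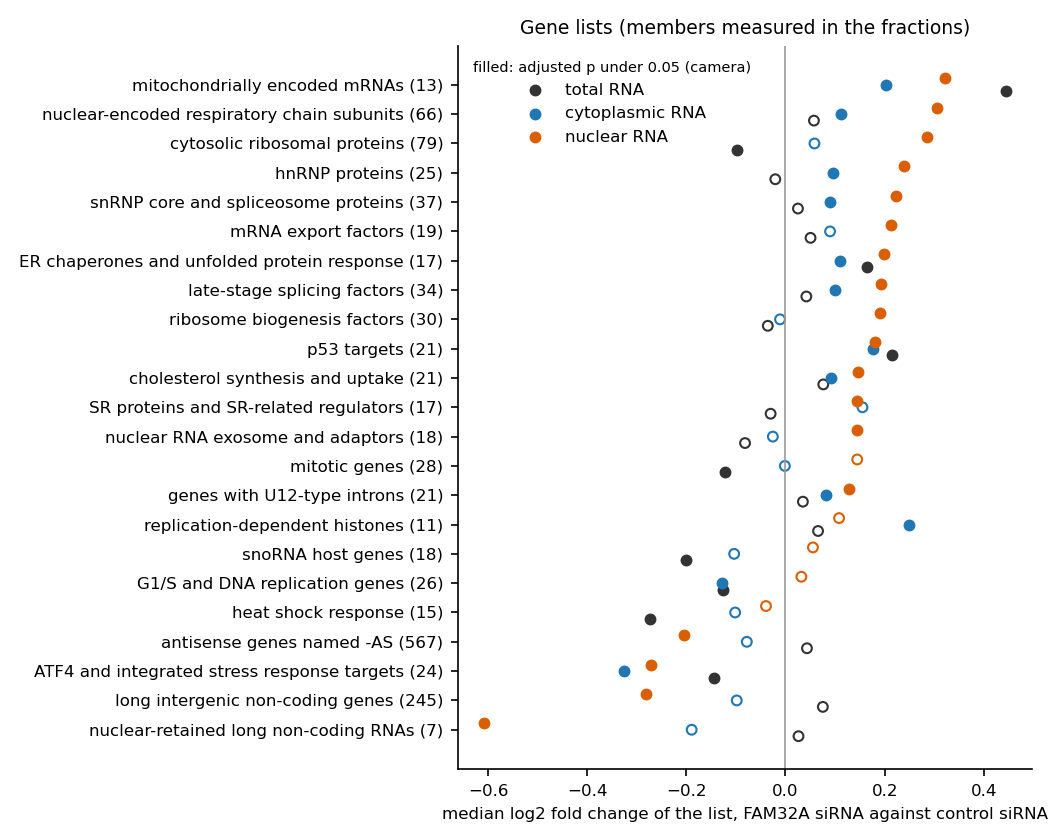
Median log2 fold change (FAM32A siRNA against control siRNA) of each gene list with an adjusted p under 0.05 in total (black), cytoplasmic (blue) or nuclear RNA (orange), with the number of measured genes in brackets and filled points for an adjusted p under 0.05 by camera with preset correlation. ATF4 targets lay at -0.15, -0.33 and -0.27 in the 3 preparations, while ribosomal proteins lay at -0.10 in total RNA and 0.29 in the nucleus.

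The ratio contrast asked which transcripts changed differently in the 2 fractions. FAM3C (1.21 ± 0.10), the endocytic adaptor NECAP1 (1.19 ± 0.08), FAM32A (1.14 ± 0.12), UEVLD (1.11 ± 0.11), the ribosomal protein paralog RPL22L1 (1.04 ± 0.16) and SPART, an endosomal protein (0.99 ± 0.08), rose most in the nucleus relative to the cytoplasm. NECAP1 rose in the nucleus (80.7 ± 5.54 to 104 ± 0.419 CPM) and fell in the cytoplasm (62.6 ± 1.29 to 34.7 ± 1.38 CPM). SLC36A1 (-1.46 ± 0.11) and WSB1, a ubiquitin ligase adaptor (-1.20 ± 0.10), fell most, WSB1 going from 60.2 ± 3.38 to 114 ± 5.29 CPM in the cytoplasm. Adjusted p values of these 8 genes ran from 6.53e-07 to 0.000672.

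Other falls in the ratio were those of ASNS (-1.05 ± 0.18, adjusted p = 0.00219), NFAT5, a regulator of the response to osmotic stress (-0.93 ± 0.20, adjusted p = 0.00946), NCR3LG1 (-1.12 ± 0.28, adjusted p = 0.0195) and the proprotein convertase PCSK7 (-0.96 ± 0.24, adjusted p = 0.0202). ASNS missed the threshold with a pseudocount of 0.1 (adjusted p = 0.155) and with voom weights (0.443), at 0.766 ± 0.0342 CPM in control cytoplasm. With no filter, NFAT5, NCR3LG1 and PCSK7 had adjusted p values of 0.0904, 0.146 and 0.141. NCR3LG1 and PCSK7 had 0.0576 and 0.0612 without nuclear knockdown replicate 1, 0.0553 and 0.0600 without cytoplasmic knockdown replicate 1, and 0.0575 and 0.0569 without cytoplasmic control replicate 2.

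Among the 17254 genes the ratio was higher for 962 and lower for 609, 7 and 12 of them at least 2-fold. Without genes that hold the 3′ UTR words described further on, 548 were higher and 356 lower. The deposited values gave 1247 and 420, voom weights 388 lower, and no filter 571 and 260. Without nuclear knockdown replicate 1 the counts were 641 and 296, without cytoplasmic knockdown replicate 1 they were 603 and 258, and without cytoplasmic control replicate 2 they were 600 and 271. The number of lower genes alone moved further without nuclear control replicate 1 (373), nuclear control replicate 3 (1021), cytoplasmic knockdown replicates 2 (1065) and 3 (356), and cytoplasmic control replicate 1 (344).

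Ribosome biogenesis factors rose in the nucleus relative to the cytoplasm in 10 of 30 cases and fell in 0 (15 and 0 when adjusted over the list alone), with a median of 0.25 (adjusted p = 8.8e-08, and adjusted p = 0.381 with an estimated correlation). DKC1 (0.43 ± 0.07), the nucleolar GTPase GNL3 (0.50 ± 0.09) and MRTO4 (0.46 ± 0.08) are examples. G1/S and DNA replication genes rose in 8 of 26 cases and fell in 0 (9 and 0 when adjusted over the list alone), with a median of 0.13 (adjusted p = 0.000194, and adjusted p = 0.445 with an estimated correlation). They included E2F1 (0.85 ± 0.11), the licensing factor CDT1 (0.68 ± 0.09) and the helicase subunit MCM5 (0.50 ± 0.07). ATF4, a single member of its list, rose in the ratio by 0.79 ± 0.11 (adjusted p = 0.000387).

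Housekeeping lists shifted the same way with few called members. The ratio was also lower for longer transcripts across genes (Spearman's rho = -0.336), and these lists were not matched for length. Ribosomal proteins rose in 3 of 79 cases (3 when adjusted over the list alone, median 0.22, adjusted p = 2.94e-06) and respiratory chain subunits in 4 of 66 (4 when adjusted over the list alone, median 0.20, adjusted p = 4.03e-05), with no falls. For both lists the adjusted p = 0.733 with an estimated correlation, and without cytoplasmic knockdown replicate 3 the preset-correlation values were 0.0573 and 0.0619. Genes named LINC fell in 13 of 245 cases and rose in 1 (6 and 0 when adjusted over the list alone), with a median of -0.16 (adjusted p = 4.03e-05, adjusted p = 0.406 with an estimated correlation, and 0.113 with no filter).

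In control cells, the comparison of nuclear with cytoplasmic RNA described the fractionation. PGGHG, a collagen glycosidase (4.83 ± 0.08, 206 ± 17.5 against 6.27 ± 0.471 CPM), CDK5RAP3 (4.68 ± 0.11), MAPK15 (4.50 ± 0.13), the microRNA host MIR503HG (4.47 ± 0.10) and YJEFN3 (4.29 ± 0.13) were the most nuclear. MTPN (-1.49 ± 0.06, 181 ± 5.34 against 512 ± 16 CPM), the RNA-binding protein YBX1 (-1.49 ± 0.07), LIN28B, a repressor of microRNA maturation (-1.42 ± 0.07), HINT3 (-1.38 ± 0.06) and RNF11 (-1.37 ± 0.06) were the most cytoplasmic. Adjusted p values of these 10 genes ran from 1.03e-17 to 2.09e-12. FAM32A lay on the cytoplasmic side (-0.74 ± 0.09).

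Of the 17254 genes, 9081 were higher in the nucleus and 5218 in the cytoplasm, 4189 and 318 at least 2-fold, with a median of 0.28 over all genes. That median moved with the scaling, to -0.13 with median-of-ratios scaling (6558 and 7996 genes), -0.12 with quantile normalization (5704 and 7900) and -0.01 on the deposited values (6041 and 5994). With a filter of 5 CPM, 5818 were higher in the nucleus, and with no filter 13830.

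Known classes of transcripts fell on opposite sides of that median. All 20 transcripts known for detained introns were nuclear (20 when adjusted over the list alone), with a median of 2.15, among them the cyclin CCNL2 (3.61 ± 0.08) and the splicing factor gene LUC7L3 (2.55 ± 0.06). The list had an adjusted p of 2.17e-07 and adjusted p = 0.295 with an estimated correlation. All 7 nuclear-retained long non-coding RNAs were nuclear (7 when adjusted over the list alone), among them NEAT1 (2.76 ± 0.10) and KCNQ1OT1 (3.09 ± 0.19), with an adjusted p of 0.0054 and adjusted p = 0.246 with an estimated correlation. Ribosomal protein mRNAs were lower in the nucleus in 73 of 79 cases and higher in 5 (73 and 5 when adjusted over the list alone), with a median of -0.82 (adjusted p = 7.01e-14, and adjusted p = 0.432 with an estimated correlation). RPL36A (2.51 ± 0.09), RPS10 (2.35 ± 0.09) and RPL17 (1.93 ± 0.11) were among those 5, and all 3 share exons with annotated read-through genes. Secretory pathway mRNAs were lower in the nucleus in 19 of 25 cases and higher in 1 (19 and 1 when adjusted over the list alone), such as KDELR2 (-1.14 ± 0.06). Their adjusted p was 1.22e-05, with adjusted p = 0.309 with an estimated correlation and 0.0884 after quantile normalization. Antisense genes named -AS were nuclear in 476 of 567 cases and cytoplasmic in 21 (478 and 21 when adjusted over the list alone), with an adjusted p of 1.3e-08 and adjusted p = 0.246 with an estimated correlation.

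Changes after FAM32A siRNA were compared between preparations across genes, which are not independent replicates. FAM32A itself stood at 18.9% of control in total RNA, 33.4% in the cytoplasm and 76.5% in the nucleus. Over 14369 genes, total and cytoplasmic log2 fold changes correlated with Pearson's r = 0.66 and Spearman's rho = 0.55. They shared 423 higher genes, where independent calls would share 76.1, and 603 lower genes, where they would share 111, with 4 genes called in opposite directions. Leaving out genes with the sites described below gave r = 0.53. Total and nuclear changes correlated with r = 0.39 and rho = 0.36, and 54 genes were called in opposite directions. Nuclear and cytoplasmic changes correlated with r = 0.63 and rho = 0.62 over 17254 genes, with 1269 shared higher and 1614 shared lower genes against 382 and 654 for independent calls.

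Because FAM32A is a spliceosome protein, protein-coding genes were grouped by the introns of their longest annotated transcript. In nuclear RNA the median log2 fold change was 0.00 for 457 genes without introns, 0.08 with 1 to 3, 0.06 with 4 to 9 and -0.08 for 5277 genes with 10 or more introns. Against other genes, those with 10 or more introns shifted down in nuclear RNA (camera adjusted p = 0.0163, and adjusted p = 0.847 with an estimated correlation) and in cytoplasmic RNA (adjusted p = 0.0459, and adjusted p = 0.542 with an estimated correlation). They did not pass in total RNA (adjusted p = 0.559) or in the ratio (adjusted p = 0.348). Genes without introns passed in none of the 4, the smallest adjusted p being 0.156 in cytoplasmic RNA. Nuclear changes were lower for longer transcripts, with a Spearman correlation across genes of -0.317. So were changes in the ratio (-0.336), against -0.0891 in cytoplasmic and -0.0842 in total RNA. No gene list above was matched for transcript length or GC content. Within 4 bins of transcript length the correlation of nuclear changes with intron number ran from -0.0774 to -0.212. With the median intron number over a gene's transcripts it ran from -0.0435 to -0.0846. Reads within introns are not in the files, so intron retention could not be measured.

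Nuclear-retained long non-coding RNAs took 0.118% ± 0.00472 (SD, n = 3) of nuclear reads after FAM32A siRNA and 0.179% ± 0.0164 in control cells (exact permutation p = 0.1, the smallest 3 against 3 allows). They took 0.0301% ± 0.00202 and 0.0373% ± 0.00307 of cytoplasmic reads (exact permutation p = 0.1) and 0.0414% ± 0.00156 and 0.0421% ± 0.00224 of total RNA reads (exact permutation p = 0.8). Ribosomal protein mRNAs took 3.37% ± 0.260 and 2.85% ± 0.300 of nuclear reads (exact permutation p = 0.2) and 5.81% ± 0.161 and 6.24% ± 0.298 of total RNA reads (exact permutation p = 0.1). Mitochondrially encoded mRNAs took 2.26% ± 0.303 of control nuclear reads and 3.56% ± 0.310 of control cytoplasmic reads (exact permutation p = 0.1). Few markers of 3 other cell types passed the filter, 0 of 8 keratinocyte and 0 of 8 hepatocyte markers, and of 11 haematopoietic markers 1 in total RNA and 2 in the fractions. Of 11 fibroblast markers 5 were measured, and COL1A1 (23.4 ± 3.81 CPM) and FBN1 (22.2 ± 0.973 CPM) were well above the filter in control total RNA. Of the 5, 3 fell in nuclear RNA, COL1A1 (-0.46 ± 0.07), FBN1 (-0.36 ± 0.09) and COL3A1 (-0.36 ± 0.10), and the list did not pass (adjusted p = 0.102).

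**Figure D4:**
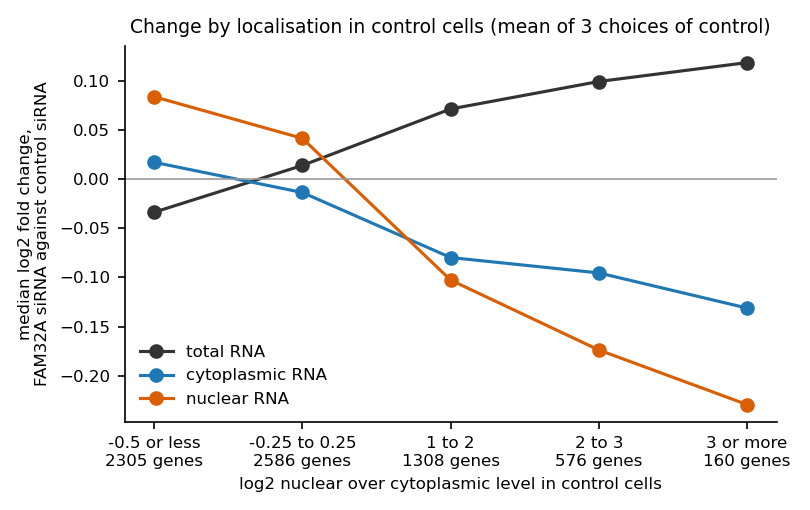
Median log2 fold change (FAM32A siRNA against control siRNA) of genes binned by log2 nuclear over cytoplasmic level in control cells, in total (black), cytoplasmic (blue) and nuclear RNA (orange), where levels of some control libraries set the bins and others the change. From the most cytoplasmic to the most nuclear bin the median went from 0.08 to -0.23 in nuclear RNA and from -0.03 to 0.12 in total RNA.

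Genes were also grouped by short words in their 3′ UTRs, a search made after the changes were seen. The words AAATGGA and AATGGAA ranked lowest and next lowest of 15711 scored 7-base words in total RNA, and of 15782 in nuclear and in cytoplasmic RNA. In the ratio these 2 words ranked highest of 15782, AATGGAA before AAATGGA. Together they form the 8-base word AAATGGAA, which FAM32A mRNA holds from base 243, before its 3′ UTR, and from base 1065 of its 1455-base transcript, within its 3′ UTR. Total RNA changes also followed GC content: they correlated with transcript GC (Spearman's rho = 0.447 over 12703 genes, against 0.114 in nuclear and 0.0498 in cytoplasmic RNA). GC-rich words such as CCCTGCC scored 20.5 there, as far from 0 as AAATGGA at -20.6, while the furthest other word with the bases of AAATGGA scored -12.9. In total RNA, 474 of 630 lower genes searched (75.2%) had such a site in the 3′ UTR, against 27.6% of all 12244 genes searched. In the cytoplasm it was 1095 of 2151 lower genes (50.9%), and in the nucleus 1164 of 2933 (39.7%), against 27.5% of 12878. Among genes searched, 353 of 851 with a higher ratio (41.5%) and 139 of 432 with a lower one (32.2%) had a site. Of genes at least 2-fold lower, 26 of 29 in total RNA and 34 of 41 in the cytoplasm had a site. Sites stood in the 3′ UTRs of SLC7A11 (2), MOCS2 (2), TTC7B (4), BTBD1 (2), GREB1L (1), NCR3LG1 (2), NECAP1 (2), UEVLD (2), SPART (8), RPS26 (1), CDC25C (1), CCNA2 (1), CHAF1B (1), XPOT (2), HYOU1 (1) and PCSK7 (1). Among genes that rose, CALU, PDIA4, SEL1L, GLIPR1, TP53INP1 and CWC15 had 1 site each and INSIG1 had 2. The annotated 3′ UTRs of FAM3C, HSPA1A, CHAC1, ASNS, ATF4, E2F1 and RPL22L1 had 0.

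The word GACGTA ranked highest of 4096 6-base words in cytoplasmic and nuclear RNA and 222nd from the highest in total RNA. In the ratio it ranked lowest. FAM32A mRNA holds it in the 3′ UTR, at base 1350. It stood in the 3′ UTR of 208 of 1616 higher genes searched in the cytoplasm (12.9%) and 120 of 598 in total RNA (20.1%), against 4.12% and 4.24% of all genes searched. For the ratio it stood in 85 of 432 lower genes searched (19.7%) and 15 of 851 higher ones (1.76%). NTN1 (2), LZTFL1 (2), PIP4K2A (1), BANF1 (1), RRS1 (1) and WSB1 (2, beside 1 of the other words) had it, while KIT, MET, SLC36A1, SNAI2 and TRIB1 had 0. In cytoplasmic RNA, genes with AAATGGAA in the 3′ UTR lay at -0.23 against genes without a site matched for 3′ UTR length, genes with 1 of the 7-base words at -0.08, and genes with GACGTA at 0.19. Genes with either 7-base word only before the 3′ UTR lay at -0.07 in cytoplasmic, -0.11 in total and -0.10 in nuclear RNA, where genes with a single 7-base word in the 3′ UTR lay at -0.08, -0.11 and -0.08. None of these differences is matched for GC content. Without genes holding any of these words, 169 genes were higher and 98 lower in total RNA, 1155 and 1325 in cytoplasmic RNA, and 548 and 356 in the ratio.

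**Figure D5:**
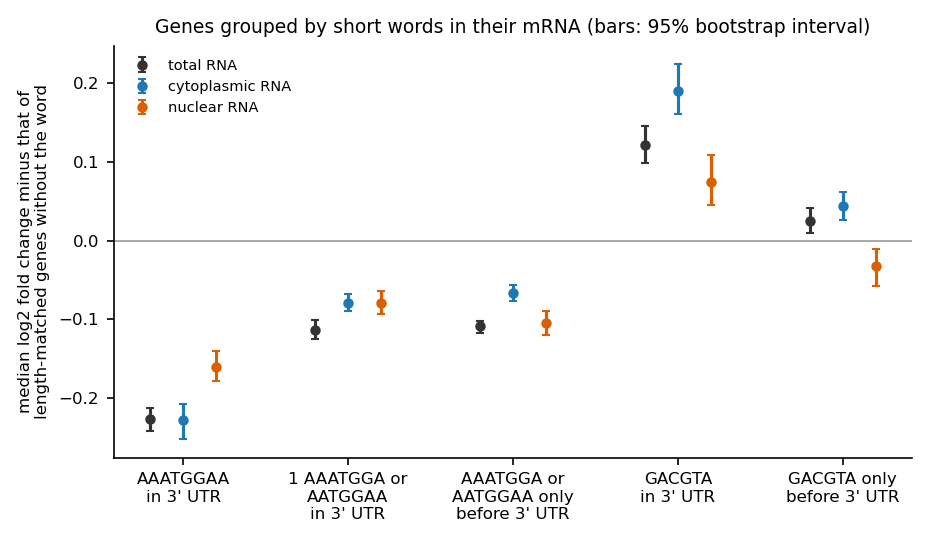
Median log2 fold change (FAM32A siRNA against control siRNA) of genes with a word minus that of genes without it matched for 3′ UTR length, with 95% bootstrap intervals, in total (black), cytoplasmic (blue) and nuclear RNA (orange). Genes with AAATGGAA in the 3′ UTR lay lowest, at -0.23 in total and cytoplasmic RNA, and genes with GACGTA there lay at 0.12 and 0.19.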

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

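Each result here stands out because the change after FAM32A siRNA differed between groups of libraries. The ratio contrast between nucleus and cytoplasm was chosen before the data were examined, and the genes it is applied to follow from the naming rule. The splits that remove the shared change were chosen after the result was seen. Values are nuclear minus cytoplasmic log2 fold changes.

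The difference lay above 0 for FAM3C (1.21), NECAP1 (1.19), FAM32A (1.14), UEVLD (1.11), RPL22L1 (1.04), SPART (0.99), BTBD1 (0.90), MOCS2 (0.89), GREB1L (0.88), GLIPR1 (0.55), TTC7B (0.47) and TRIB1 (0.29). Of these, GLIPR1 and TRIB1 rose in both fractions and more in the nucleus. FAM3C, MOCS2, BTBD1, GREB1L, TTC7B, UEVLD, SPART and FAM32A had the lower value in the cytoplasm.

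It lay below 0 for SLC36A1 (-1.46), WSB1 (-1.20), NCR3LG1 (-1.12), ASNS (-1.05), PCSK7 (-0.96), NFAT5 (-0.93), KIT (-0.85), NTN1 (-0.77), SLC5A4-AS1 (-0.69), LZTFL1 (-0.66), PIP4K2A (-0.55) and MET (-0.49). NTN1, PIP4K2A, KIT and LZTFL1 rose in the cytoplasm by more than in the nucleus. The limits of NCR3LG1, ASNS, PCSK7 and NFAT5 are given with the ratio above.

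Among gene lists the median difference was 0.25 for ribosome biogenesis factors, 0.22 for ribosomal proteins, 0.21 for immediate early genes, 0.20 for respiratory chain subunits, 0.17 for the nuclear exosome, 0.14 for hnRNP proteins, 0.13 for G1/S genes, 0.13 for snRNP proteins and 0.10 for late-stage splicing factors. It was -0.16 for genes named LINC, -0.15 for transcripts known for detained introns and -0.10 for antisense genes named -AS. None of these 12 lists kept its call with an estimated correlation, where the smallest adjusted p was 0.381. The detained-intron list also lost its call without nuclear knockdown replicate 2 (adjusted p = 0.12), nuclear control replicate 3 (0.0561), cytoplasmic knockdown replicate 1 (0.0898) or cytoplasmic control replicate 3 (0.05005), and the -AS list with no filter (0.0816) and quantile normalization (0.102). The snRNP list lost it with a filter of 5 CPM (0.0725) and without nuclear knockdown replicate 2 (0.0859), nuclear control replicate 1 (0.06), cytoplasmic knockdown replicate 3 (0.0619) or cytoplasmic control replicate 2 (0.111). Immediate early genes lost it with a filter of 5 CPM (0.0606), on the deposited values (0.0641) and without genes that hold the words (0.195), and late-stage splicing factors with a filter of 5 CPM (0.0602). With fry the adjusted p was 0.105 for snRNP proteins, 0.14 for detained introns, 0.106 for -AS genes, 0.366 for ribosomal proteins and 0.326 for respiratory chain subunits.

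In 3 genes all nuclear knockdown libraries moved against all total RNA libraries, a difference that was not tested. These were RPL22L1 (0.92 in the nucleus and -0.58 in total RNA, 1.49 apart), NECAP1 (0.36 and -0.67, 1.03 apart) and WSB1 (-0.29 and 0.68, -0.97 apart). Total RNA and fractions are separate sets of libraries, in which FAM32A fell to different shares of control.

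The ratio called 1571 genes, and 6 of 100 splits of the libraries called as many, the real one among them, with 8858 at most in another. Splits of this contrast mix in the change that both fractions share. With that change removed, 1561 genes were called, and only the real split, 1 of 100, called as many, with 10 at most in another.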

How the results depend on the processing

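The intended tests with edgeR (TMM scaling) and DESeq2 were not run because the files hold no counts, and the same choices were varied in limma. Quantile normalization and voom weights outside total RNA and the ratio were chosen after the data were seen. So were the replicate block within the cytoplasm alone and leaving out genes with the 3′ UTR words. The fit of deposited values was the fallback as it had been worded beforehand. No called list turned direction under median-of-ratios scaling, quantile normalization or the deposited values. The cause of each change below was not tested, except that leaving out genes or libraries leaves fewer to test.

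Without a filter, 279 genes were higher and 405 lower in total RNA, 571 and 260 in the ratio, and 13830 were higher in control nuclei, against 5818 with a filter of 5 CPM. Median-of-ratios scaling gave 2884 higher genes in the cytoplasm and 7996 lower genes in control nuclei. The deposited values gave 2657 lower genes in the nucleus and 6041 higher in control nuclei, and quantile normalization 5704 higher and 7900 lower there. Voom weights gave 388 lower genes in the ratio. Without genes that hold the words, 169 were higher and 98 lower in total RNA, 1155 and 1325 in the cytoplasm, and 548 and 356 in the ratio, and total and cytoplasmic changes correlated with r = 0.53. Without 1 library, total RNA gave 163 to 1441 higher and 269 to 1087 lower genes, and the ratio 600 to 1370 and 258 to 1065.

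Residuals of the same replicate number went together only in the cytoplasmic libraries, which chance can give with so few libraries. The replicate block in that fraction alone gave 2768 higher genes. The fraction alone without the block gave 1910. The U12-type intron list lost its call in both fits (adjusted p = 0.0587 and 0.0718), and of 3 lists that newly passed with the block 1 did so without it too. The block ended no call of a named gene. In the other comparisons libraries share only a number, and a replicate block gave 892 higher and 798 lower genes in total RNA, 3603 and 4335 in the nucleus, and 856 and 511 in the ratio. There the libraries did not all correlate best with their own number.

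The difference between control fractions of genes with 10 or more introns and genes without, 0.09, was 0.24 with quantile normalization, 0.23 with the median intron number, 0.18 without genes that hold the words, and 0.04 to 0.15 without 1 library. Reversed values were those of SARNP in the ratio (-0.65 with voom weights, adjusted p = 0.682) and, between control fractions with quantile normalization, of H2BC6 (-0.10), H2BC15 (-0.0479), H3C6 (-0.17) and CD14 (-0.10). With fry, the interferon list (median -0.16) and the exon junction complex list (median -0.12) pointed up between control fractions (adjusted p = 5.58e-06 and 0.0153).

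All 73 list calls were lost with an estimated correlation. Of these, 22 were lost with quantile normalization, 19 with a filter of 5 CPM, 16 with fry, 16 without some library, 11 without genes that hold the words, 10 on the deposited values, 5 without a filter, 2 with median-of-ratios scaling and 0 with a pseudocount of 0.1. Of 631 called results of named genes, 106 were lost without some library, 90 without a filter and 23 with quantile normalization. The deposited values lost 19, median-of-ratios scaling 17, voom weights 13 and a pseudocount of 0.1 lost 12. Without genes that hold the words, 27 were lost and 394 kept. The others belong to genes that this setting leaves out, so they were not tested there. Total RNA, at 19.8 to 20.1 M reads, and the ratio had the least power: 81% and 40% of simulated 1.5-fold changes were called there.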

Other observations

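All tests on words in 3′ UTRs and on nuclear-enriched transcripts were designed after the log2 fold changes had been seen. For the words, the predictions on site strength and on the number of GACGTA sites were written before their values were computed, as was the one on transcript length. The predictions on base composition, loss of the protein, mixing of fractions and whole-cell level were written after.

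Single members of lists that did not pass in the same preparation also changed. RPN2, a subunit of the oligosaccharyltransferase with AAATGGAA once in its 3′ UTR, changed by -1.12 ± 0.06 in total RNA, -1.23 ± 0.05 in the cytoplasm and -0.84 ± 0.05 in the nucleus. MYC, with neither AAATGGA nor AATGGAA there, rose by 1.04 ± 0.05 in the nucleus and 0.69 ± 0.05 in the cytoplasm, where the immediate early list that holds it did not pass (adjusted p = 0.0738 and 0.774), though it did in the ratio (adjusted p = 0.0186, and adjusted p = 0.445 with an estimated correlation). IFIT5, an interferon-induced RNA-binding protein with 3 sites, 2 of them AAATGGAA, changed by -0.76 ± 0.11 in total RNA, while the interferon list did not pass (adjusted p = 0.433).

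Several RNA processing lists were called in the nucleus with less margin. Genes with U12-type introns rose in 8 of 21 cases and fell in 0 (8 and 0 when adjusted over the list alone), among them E2F4 (0.42 ± 0.06), with an adjusted p of 0.0108 and adjusted p = 0.273 with an estimated correlation. The value was 0.0733 with quantile normalization and 0.0746 without genes that hold the words. Export factors rose in 11 of 19 cases and fell in 3 (11 and 3 when adjusted over the list alone), among them CHTOP (0.41 ± 0.05), with an adjusted p of 0.0278 and adjusted p = 0.161 with an estimated correlation. It was 0.153 with a filter of 5 CPM, 0.105 on the deposited values, 0.0931 with quantile normalization and 0.167 without genes that hold the words. SR proteins rose in 8 of 17 cases and fell in 2 (8 and 3 when adjusted over the list alone), with TRA2B (0.51 ± 0.05) up and ACIN1 (-0.41 ± 0.06) down. The SR list had an adjusted p of 0.0401, with adjusted p = 0.319 with an estimated correlation. It was 0.122 with a filter of 5 CPM, 0.0959 with quantile normalization, 0.134 without genes that hold the words, and 0.0575, 0.071, 0.0607 and 0.0511 without nuclear knockdown replicates 1 and 3 and nuclear control replicates 1 and 3. The nuclear exosome and its adaptors rose in 8 of 18 cases and fell in 2 (8 and 2 when adjusted over the list alone), with the subunit EXOSC4 (1.16 ± 0.11) and the cofactor C1D (0.99 ± 0.09) up and the adaptor ZFC3H1 (-0.48 ± 0.08) down. The median was 0.15, with an adjusted p of 0.0401 and adjusted p = 0.301 with an estimated correlation. The value was 0.129 with a filter of 5 CPM, 0.0603 on the deposited values, 0.105 with quantile normalization, 0.0594 without genes that hold the words, and 0.0504, 0.0706 and 0.0519 without nuclear knockdown replicates 1 and 3 and nuclear control replicate 1.

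The first pattern is the fall of genes with AAATGGA or AATGGAA in the 3′ UTR, words that FAM32A mRNA holds at several places, though the siRNA sequence is not given. Pairing with an siRNA seed complementary to them predicts that genes with the full 8-base word fall more than genes with 1 of the 7-base words. In the cytoplasm they lay -0.149 apart (95% interval over genes -0.174 to -0.125), so this explanation could hold. The 8-base genes may hold several sites, and genes with 2 or more sites lay at -0.192, so site strength is not told apart from site number. This comparison also used the genes in which both words were picked, so it is a weak test. Genes with a word only before the 3′ UTR were lower as well, at -0.07 in the cytoplasm and -0.11 in total RNA against genes matched for 3′ UTR length. They were not matched for transcript length or GC content, so whether their shift belongs to the same pattern cannot be told. In the ratio they lay at -0.0390, where genes with a site in the 3′ UTR lay at 0.0380. Base composition alone is excluded in the cytoplasm: with the words chosen on 6439 genes and scored on the other 6439, 0 of 103 other words of the same bases scored as low (-12.5 against -6.36 for the furthest other, and -12.2 against -5.50 with the gene sets swapped). Loss of the FAM32A protein remains open, because no library used another siRNA against FAM32A. Genes with a site had a ratio of 0.0380 (0.0297 to 0.0484) against matched genes, a value that does not decide it.

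The second pattern is the rise of genes with GACGTA in the 3′ UTR, a word that the 3′ UTR of FAM32A holds too. If the control siRNA carried the complementary seed, genes with 2 or more sites should lie above genes with 1, and they did by 0.0774 with a 95% interval of -0.0496 to 0.214. The prediction made beforehand counted an interval that includes 0 against this explanation, a bound that was wrong, since only 26 genes have 2 or more sites and the interval decides nothing. Base composition alone is excluded in the same way, with 0 of 179 other words as high (12.1 against 4.72, and 8.48 against 4.28 with the gene sets swapped). Loss of the FAM32A protein could not be told apart, because no library used another control siRNA. Genes with a site had a ratio of -0.126 (-0.153 to -0.106), which does not decide it.

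The third pattern is the lower nuclear level of nuclear-enriched transcripts after FAM32A siRNA. The values argue against more cytoplasmic RNA in the knockdown nuclear libraries as the whole cause but not as a part of it. Against length-matched genes found equally in both fractions, a share of 18.2% would give the observed fall and place cytoplasm-enriched genes at 0.155. Yet they lay at 0.00456, a gap of -0.1505. The outer limits of its intervals over genes, for 3 choices of control, were -0.173 and -0.131. These limits leave out the uncertainty of the share and the spread between libraries. Before matching, the median change of cytoplasm-enriched genes was 0.0836. Some lists on the cytoplasmic side in control cells rose in the knockdown nuclear libraries. Their medians were 0.29 for ribosomal proteins (-0.82 between control fractions), 0.31 for respiratory chain subunits (-0.43) and 0.32 for mitochondrially encoded mRNAs (-0.23). Not every list followed its side: transcripts known for detained introns, all nuclear in control cells, lay at -0.045 in the nucleus (camera adjusted p = 0.697). Transcript length is excluded as the whole cause too, since the difference from length-matched genes was -0.198 (outer limits -0.232 to -0.167). A lower level in whole cells cannot be judged: the same genes lay at 0.0825 (outer limits 0.0691 to 0.0948) in total RNA and at -0.0865 in the cytoplasm. Whether total RNA and fractions were taken at the same time stands only in the series description, and FAM32A fell further in total RNA than in either fraction.

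Splits of 3 against 3 libraries are too few, 10 in all, for a share under 0.05. The real split was the only one to call as many genes, 1 of 10, in nuclear RNA (8079, with 0 at most in another), in cytoplasmic RNA (4353, with 0) and between the control fractions (14299, with 0). In total RNA 2 of 10 splits called as many: the real one called 1325, and the one that sets control 1 and knockdown 1 and 2 against the others called 1411, so the total RNA libraries also divide along something other than the siRNA.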
